A study of Drosophila melanogaster with 2 samples.

How the data were processed

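ChIP-seq peak lists from 2 biological replicates of whole embryos expressing Camta-eGFP were used. Per the labels, chromatin was sheared by sonication to a size range of 200 to 800 (unit not stated), and each replicate was 1 library. Per the file records, a relaxed list of peaks and background was made for each replicate and for both replicates pooled, on dm6 each from the alignments and 1 further file, the same for all 3 lists and taken here to be the control since the records do not name its kind, and the optimal IDR list was derived from those 3 lists. The aligner, the peak caller and their versions are not given in the sources used here. Each list was deposited on 2 genome builds, dm6 and dm3. The control experiment itself was not analysed here.

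The signal value of a region is the authors' own, as deposited; how it was scaled is not given in the sources used here. The q value of a region was deposited by the authors as its −log10. The deposited summit is an offset in bases from the region's start, counted from 0; positions are printed here counted from 1. Signal values of different lists may be on different scales, so their levels were not compared between lists; between the replicates they were only correlated, by ranks and by log10 values. The optimal IDR peaks were found to be the 4033 regions of highest signal value among the 30000 of the pooled relaxed list. On dm6, 5758 pooled relaxed regions had a q value of 0.01 or less, among them all IDR peaks. The median width of an IDR peak was 424 bp, and 6 IDR regions were listed more than once with different summits; each summit was kept. No file gives read counts or depths, so the depth of each replicate is unknown and intervals cover only the number of peaks or genes.

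The annotation was Ensembl release 115 on BDGP6.54 and the sequence the RefSeq Release 6 assembly, which have dm6 coordinates. Transposable elements and pseudogenes were left out. A summit within 500 bp of the start of any annotated transcript was called promoter, and other summits were placed, in this order, in coding exon, 5' UTR, 3' UTR, non-coding exon, intron or intergenic sequence. No annotation of dm3 was used, and no coordinate was converted between builds.

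Replicates were compared over the 4033 strongest regions of each relaxed list, as many as there were IDR peaks. A region counted as shared when at least 50% of its length was covered by a region of the other list. The level under random placement came from 1000 circular shifts within each arm, which do not keep regions at promoters. On dm3, whose arm lengths were not used here, arms were taken to end 1000 bp past the last listed region. The background for location was every pooled relaxed region that overlapped no IDR peak. Motifs were searched on both strands within 50 bp of the summit, a window of 101 bp, and in windows centred 500 bp to either side, with an exact McNemar test for each flank. A motif counted as different at an adjusted p under 0.05 and a fold of at least 1.5 in either direction. Windows were also compared with 10 dinucleotide-preserving shuffles of themselves. Gene lists were compared with all other protein-coding genes on the 6 arms by Fisher's exact test. Permutation tests drew 100000 resamples. Intervals have a confidence level of 95%, by Wilson's method for shares and the normal approximation on the log scale for odds ratios.

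Genes named in the text follow a rule fixed before the data were examined: the nearest gene of the 15 strongest promoter peaks, the gene holding or nearest to the 5 strongest other peaks, Camta, Fbxl4, ninaE and Cam whatever their values, and up to 4 members of each list with the highest promoter signal. Of the listed symbols, 3 were not matched to a single annotated gene and were left out: Hop, calypso and Dl. Alternatives covered the overlap rule, the number of regions taken, the promoter window (250 and 1000 bp) and the motif window (100 and 25 bp). They also covered the flank distance (1000 bp), the background, the strongest 2016 IDR peaks alone, the genome build and each replicate's list alone. The IDR threshold itself was not varied. Leaving out a replicate meant using the 4033 strongest regions of the other, since the IDR list needs both.

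The calculations were tested on simulated data. In 200 simulated runs of the gene list comparison, the enriched list was recovered in 100% and the mean share of false calls was 5.46%. The simulated lists were larger than most of the lists used here. The enriched one was set near the bound share of the cytosolic ribosomal proteins, so the recovery does not apply to smaller lists or weaker enrichment. In 200 runs of the McNemar test used for the motif panel on equal shares, 2.5% passed an unadjusted threshold of 0.05. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and samtools 1.23.1 were used.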

Results

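Chromatin immunoprecipitation and sequencing (ChIP-seq) was carried out on whole *Drosophila melanogaster* embryos of mixed sex, collected 0 to 24 h after laying. The embryos carried a fusion of Camta to enhanced green fluorescent protein (eGFP), made by an eGFP exon placed in an intron of the gene, and an antibody against GFP was used for the precipitation. Camta is the fly member of the calmodulin-binding transcription activators, proteins that bind a CGCG box in vitro and bind calmodulin. There was a single group of 2 biological replicates, numbered 2 and 3 in the labels. The deposited peak lists give no read counts, so sequencing depth is unknown. Positions are on genome build dm6 unless dm3 is named, and each peak's signal value is the authors' own, used here to rank, describe and compare peaks within a list and to correlate the replicates, never as a difference in level between lists.

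Both replicates placed most of their strongest regions at shared sites. The strongest peak of the list that passed the authors' irreproducible discovery rate (IDR) threshold, in an intron of ush on 2L with its summit at position 481057 and 1369 bp upstream of the nearest start site of cbt, ranked 2 in replicate 2 and 1 in replicate 3. The peak at px, a gene of wing vein patterning, ranked 1 and 2, and the peak at CG14100 ranked 3 in both. Of the 4033 strongest regions of replicate 2, 70.9% were covered over at least 50% of their length by one of the 4033 strongest regions of replicate 3, against a mean of 1.12% and a maximum of 1.81% over 1000 circular shifts of the list within each chromosome arm. The one-sided permutation p was 0.000999, the smallest that the shifts can give. The shifts do not keep regions at promoters, so a preference for promoters that both lists share can add to the overlap. Per the file records, the lists of both replicates were made with 1 further file in common, taken here to be the control, and part of the overlap can come from what they share.

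Peak strength was correlated between the replicates. Over the 4029 IDR peaks with a region in both replicates' relaxed lists, which hold peaks and background candidates before thresholding, Spearman's rho of the signal values was 0.688 and Pearson's r of their log10 values was 0.773. Each had a permutation p of 1e-05, the smallest that 100000 resamples can give. The correlation is across peaks, which are not independent replicates, and part of it can come from the file that both lists share, which the permutations do not take into account. Single peaks differed in rank, as at Cdk1 (6998 in replicate 2 and 1120 in replicate 3) and numb (4463 and 783). Of the 4033 IDR peaks, 3003 were covered by the 4033 strongest regions of both replicates, 983 by those of 1 replicate only and 47 by neither.

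**Figure D1:**
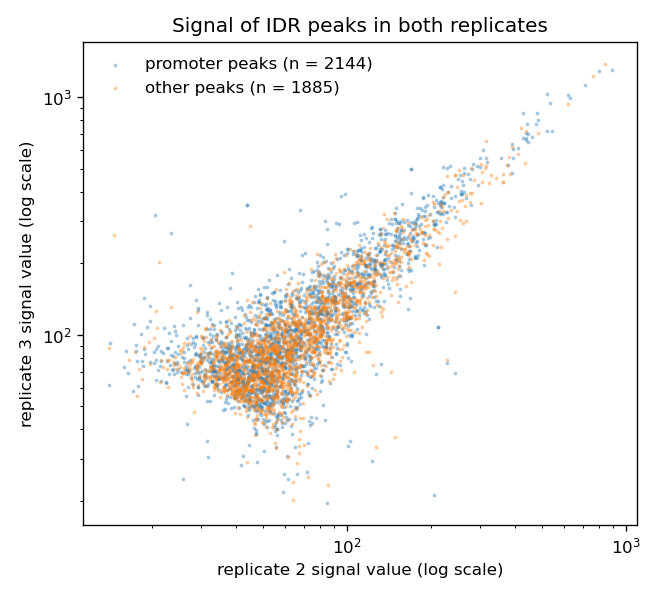
Signal value of each IDR peak in replicate 2 (x axis) and replicate 3 (y axis), both on a log scale in the authors' arbitrary units, with promoter and other peaks in separate colours. The points spread along a rising diagonal (Spearman's rho 0.688 over 4029 peaks).

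Where in the genome the tagged protein was enriched was asked next. IDR peaks lay mostly at promoters. Of the 4033 summits, 2148 (53.3%, 95% Wilson interval 51.7 to 54.8) were within 500 bp of an annotated start site, against 26.5% of the 25098 regions of the pooled relaxed list that overlapped no IDR peak. The odds ratio was 3.17 (95% interval 2.96 to 3.39, Fisher's exact test, two-sided, p = 2.77e-240). Introns held 32.9% of the IDR summits and 33.4% of the other relaxed regions, and intergenic sequence 11.8% and 16.1%. Coding exons held 9 IDR summits (0.223%) against 4990 (19.9%) of the other relaxed regions, an odds ratio of 0.00901 (95% interval 0.00503 to 0.018). The 3' UTR share was 0.645% against 2.29%. Against an equal number of the strongest other relaxed regions, 42.9% of which lay at promoters, the odds ratio for promoters fell to 1.51.

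**Figure D2:**
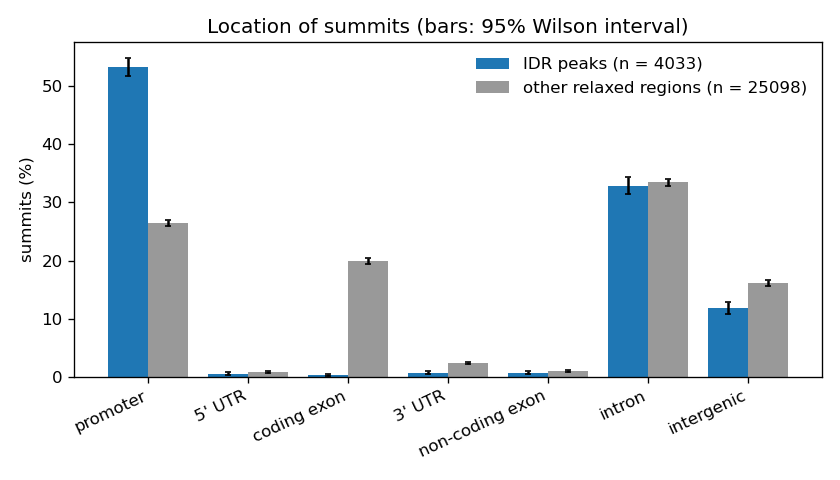
Share of summits (y axis, percent) in each annotated location (x axis) for the 4033 IDR peaks and for the 25098 other relaxed regions; error bars are 95% Wilson intervals. Promoters held 53.3% of IDR summits and 26.5% of the others, and coding exons 0.223% and 19.9%.

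The strongest promoter peak was that of px, on 2R from 22514085 to 22514523, with a signal value of 2186 and its summit 204 bp upstream of a start site. CG14100 followed on 3L, from 19590416 to 19590825, with a signal value of 2091. Ugalt, which encodes a UDP-galactose transporter, had a peak on X from 2703675 to 2704087 with a signal value of 1841, and its summit lay 42 bp upstream of the start site. The peak at Chro, which encodes the chromodomain protein Chromator, lay on 3L from 22878699 to 22879104 with a signal value of 1635, within 500 bp of a start site of Ssl1 as well. At ph-p, a gene of the Polycomb group, the peak on X from 2137148 to 2137556 had a signal value of 1589 and its summit lay 478 bp upstream of a start site. Next came mRpL41, a mitochondrial ribosomal protein gene, on 2R from 15217555 to 15217969 with a signal value of 1550.2, and PNPase, which encodes a polynucleotide phosphorylase, on 3R from 31404475 to 31404879 with 1472.

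Art3, an arginine methyltransferase gene, shared a peak of signal value 1333 on 3R with mRpS10. The other promoters among the 15 strongest were CG31145 with a signal value of 1283, Tcs5 with 1279, CG1888 with 1255, CG9147 and the casein kinase gene gish with 1244 each, and the non-coding RNA genes lncRNA:CR44619 with 1209 and lncRNA:CR31840 with 1152. Among peaks away from start sites, the one in an intron of ush had a signal value of 2218, on 2L from 480857 to 481313. An intron of CG11050 on 2L held a peak of 1981 from 6612464 to 6612921. An intron of Lk6, a kinase that phosphorylates the translation factor eIF4E, held one of 1557 on 3R from 11760853 to 11761240. The others were an intergenic peak of 1189.7 on 2R, from 13035157 to 13035528, whose nearest start site was that of CG13323 at 11909 bp, and a peak of 1157 in introns of HmgZ and HmgD, which encode HMG-box proteins and overlap there, on 2R from 21703151 to 21703667.

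Over all IDR peaks, promoter and other peaks did not differ detectably in strength, but under 3 of 5 alternatives the promoter peaks were stronger. The median signal value was 148.9 over 2148 promoter peaks and 144.5 over 1885 other peaks, a difference of 0.0132 in log10 (permutation test, two-sided, p = 0.149). The same permutation test passed among the strongest 2016 peaks, at 0.0337 (p = 0.00062), with a promoter window of 1000 bp, at 0.0203 (p = 0.0311), and in the 4033 strongest regions of replicate 3, at 0.0297 (p = 6e-05), and not in those of replicate 2, at 0.000526 (p = 0.936); whether the replicates differ in this was not tested. Most promoter summits sat upstream of the start site. A summit between divergent start sites is upstream of both. The binomial test given here takes both sides as equally likely and used no background, so it does not allow for this. Over the 2045 peaks within 500 bp of a start site of a protein-coding gene, the median summit lay 88 bp upstream of it (quartiles at 177 and 21 bp upstream), and 1658 (81.1%) were upstream against 380 downstream (exact binomial test, two-sided, p = 1.1e-189).

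**Figure D3:**
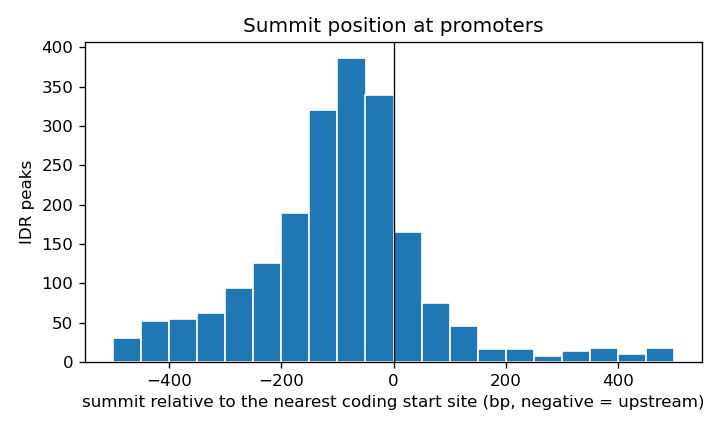
Number of IDR peaks (y axis) by distance of the summit from the nearest start site of a protein-coding gene (x axis, bp in bins of 50, negative values upstream). Of the 2045 peaks, 1658 lie upstream, with the median at 88 bp.

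Camta's own promoter was among the bound ones. Its peak on 2R, from 9445782 to 9446205, had a signal value of 265 and rank 714 of the 4033 IDR peaks, with the summit 52 bp upstream of the start site. Fbxl4 encodes an F-box protein and is a target of Camta in photoreceptors. A peak on X from 14238050 to 14238473, with a signal value of 316, had its summit 339 bp upstream of the start site of Fbxl4. The summit lay inside the gene Dus2 and within 500 bp of a start site of Dus2, so the peak cannot be assigned to Fbxl4 alone. Cam, the calmodulin gene, had no IDR peak at a promoter. It held one in an intron on 2R at 12261629, 1597 bp downstream of a start site, with a signal value of 561 and rank 133, and a weaker one in its 3' UTR with 102.7. At its promoter the pooled relaxed list held 1 region, of signal value 80.0172. For ninaE, which encodes the main rhodopsin of the fly eye, no region of either list lay at the promoter, and the nearest IDR summit was 4010 bp from its start site.

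Which sequences lay at the summits was tested with a panel of 18 motifs fixed before the data were examined, within 50 bp of the summit against windows of the same width 500 bp to either side. The DRE (TATCGATA), the site of the promoter factor DREF, was the most enriched, at 2.16% of summits against 0.31% of flanks, a fold of 6.96 (exact McNemar test, adjusted p = 7.53e-12). Motif 1, the site of M1BP (GGTCACAC), stood at 1.29% against 0.347%, a fold of 3.71 (exact test, adjusted p = 1.82e-05), and the TATA box at 17.6% against 10.8%, a fold of 1.63 (adjusted p = 2.8e-16). The CGCG box (VCGCGB) was rarer at summits than in flanks, at 6.2% (95% Wilson interval 5.5 to 6.99) against 10.7%, a fold of 0.579 (exact test, adjusted p = 4.47e-12), and so was the CCGG control of the same composition, with a fold of 0.43 (adjusted p = 1.83e-20). Without replicate 3 the CGCG box, at a fold of 0.764, and the TATA box, at 1.39, no longer reached the fold of 1.5 in either direction that a call required, and among the strongest 2016 peaks Motif 1, at 2.67, was no longer called. Adjusted p-values are from exact McNemar tests, two-sided, with Benjamini-Hochberg adjustment over the 18 motifs and the larger p of both flanks.

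DRE-type motifs and Motif 1 were enriched over flanks at promoter peaks and not detectably at others. The TATA box, the CGCG box and the CCGG control went the same way at both. The differences between locations were not tested. At the 2148 promoter peaks the DRE reached 3.96% against 0.372% in flanks, a fold of 10.6, and at the 1885 other peaks 0.106% against 0.239%. The shorter DRE core CGATA stood at 23.7% of promoter summits, a fold of 2.01, and at 10.4% of the others, a fold of 0.867. Motif 1 had folds of 4.57 and 1.14. Promoter peaks were compared here only with their own flanks and not with promoters that lack an IDR peak. The folds of the DRE and Motif 1 therefore cannot tell bound promoters from promoters in general. The TATA box had folds of 1.71 and 1.55 at promoter and other peaks, the CGCG box 0.581 and 0.576, and the CCGG control 0.486 and 0.346. Over all peaks, 13 of the 18 motifs did not meet both criteria. Among them GAGA, the Trl site, had a fold of 0.714, the GCGC control 0.831 and the DRE core 1.47. These passed the p threshold and missed only the fold (exact McNemar tests, adjusted p = 3.73e-07, 0.00998 and 8.63e-11). The CTCF core had a fold of 1.37, the heat shock element 1.43, the ETS core 3.11 at 14 of 4033 summits, and the initiator and Su(H) sites 1.04 each. CAGGTA, the zld site, stood at 0.7, the E-boxes CACGTG and CAGCTG at 0.661 and 0.946, CRE at 0.667 and AP-1 at 0.929. By location, GAGA and CAGGTA met both criteria at 1 of them. GAGA was rarer than in flanks at other peaks (0.628, exact McNemar test, adjusted p = 9.42e-07) and was not called at promoter peaks (0.801). CAGGTA was rarer at promoter peaks (0.519, exact McNemar test, adjusted p = 0.0189) and was not called at other peaks (1.03).

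The directions of the CGCG box and of the TATA box depended on the background. Summit windows held 35.9% G and C on average against 43.5% in flanks and 45.4% in the other relaxed regions. Against relaxed regions of the same GC content, chosen as a background after seeing the data, the CGCG box was more frequent at the summits, at 6.2% against 5.2%, a fold of 1.19 (Mantel-Haenszel odds ratio 1.24, 95% interval 1.07 to 1.43). The GCGC control of the same composition was also more frequent there, at 9.89% against 6.9% (odds ratio 1.59, 1.41 to 1.79), and the CCGG control did not differ detectably, at 4.29% against 4.54% (odds ratio 0.944, 0.798 to 1.12). The TATA box was less frequent than in these matched regions, at 17.6% against 19.7% (odds ratio 0.863, 0.783 to 0.95), while the DRE and Motif 1 stayed more frequent, with odds ratios of 2.55 (1.97 to 3.29) and 1.97 (1.44 to 2.69). The match was on GC content alone, and promoters held 53.3% of IDR summits against 26.5% of the other relaxed regions before matching. Part of each difference from the matched regions can therefore come from location, which was not separated. The TATA box was about as frequent in dinucleotide-shuffled copies of the summit windows, at 17.4%, as in the windows themselves, at 17.6%, while the DRE was 15.8 times more frequent than in shuffled copies and Motif 1 10.8 times.

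The CGCG box was less frequent in the strongest than in the weakest of 4 groups of peaks, without a steady fall in between. With the IDR peaks ranked by signal value and parted into 4 groups of nearly equal size, it was present in 7.83% of the weakest group, 7.44% and 4.27% of the next groups and 5.26% of the strongest, an odds ratio of 0.653 (95% interval 0.458 to 0.938, Fisher's exact test, two-sided, p = 0.0241) between strongest and weakest. Split the same way, the strongest 2016 peaks gave no detectable difference (odds ratio 0.754, Fisher's exact test, p = 0.503). Among promoter peaks the shares were 5.4% and 11%, an odds ratio of 0.462 (Fisher's exact test, p = 0.00115), and among other peaks 4.25% and 4.66%, an odds ratio of 0.907 (p = 0.875). Whether promoter and other peaks differ in this was not tested.

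**Figure D4:**
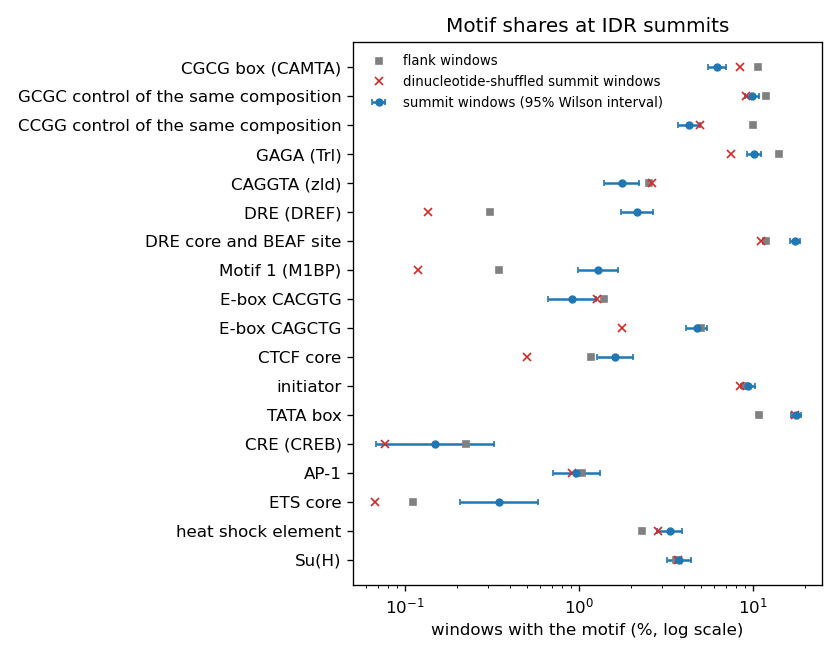
Share of windows with each motif of the panel (x axis, percent on a log scale) at IDR summits, in flanks and in dinucleotide-shuffled summit windows; error bars are 95% Wilson intervals. The DRE stands at 2.16% at summits and 0.31% in flanks, and the CGCG box at 6.2% and 10.7%.

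Which genes were bound was asked with 18 gene lists fixed before the data were examined. Of 13945 protein-coding genes, 2619 (18.8%) had an IDR summit within 500 bp of a start site. The cytosolic ribosomal protein genes stood far above this: 68 of 86 were bound (79.1%, 95% Wilson interval 69.3 to 86.3), an odds ratio of 16.7 against the other genes (Fisher's exact test, two-sided, adjusted p = 1.51e-32 over the 18 lists). RpS27 had a signal value of 707, RpL32 638.6, RpL23A 572 and RpL7 523. Of the mitochondrial ribosomal protein genes 25 of 73 were bound (34.2%), an odds ratio of 2.26 (Fisher's exact test, adjusted p = 0.00656), with mRpL41, mRpS10, mRpS23 and mRpL23 the strongest, the last 2 at 1109 and 855. Each of these 4 peaks also lay within 500 bp of another gene's start site, and with each peak counted only for its nearest start site the list fell to 11 of 73, an odds ratio of 1.1 (Fisher's exact test, adjusted p = 0.843), and was no longer called.

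Polycomb and trithorax group genes, which keep gene states through cell division, were bound in 11 of 22 cases, an odds ratio of 4.34 (Fisher's exact test, adjusted p = 0.00547), with ph-p at 1589, Trl at 347, brm at 311 and Sfmbt at 242. Cell cycle genes were bound in 11 of 26 cases, an odds ratio of 3.18 (exact test, adjusted p = 0.0172), with Dp at 337, aurA at 196, RnrS at 168 and Cdk1 at 162. Odorant and gustatory receptor genes lay at the other end, with 0 of 119 bound (upper Wilson bound 3.13%, exact test, adjusted p = 2.04e-10).

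The cytosolic ribosomal protein list was called under every alternative run, and each of the other 4 lists lost its call under at least 1. Without replicate 3 the cell cycle list lost its call (10 of 26, exact test, adjusted p = 0.0612), and among the 7414 genes with a relaxed region at the promoter, of which 10 were odorant or gustatory receptors, the cytosolic ribosomal protein list alone passed, with 68 of 80 bound and an odds ratio of 10.6 (exact test, adjusted p = 7.49e-19). Many of the named peaks lay within 500 bp of start sites of more than 1 gene, and such a peak was counted for each. Examples were RpL32 and CG7943, Cdk1 and mRpS7, brat and Polr1D, and mbc and Nup98-96.

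The 13 other lists did not differ detectably from the remaining genes. Proteasome genes were bound in 10 of 32 cases, with Rpn5 at 353, Rpn3 at 218, Rpn13 at 184 and Rpn6 at 146. Each of these named peaks also lay within 500 bp of another gene's start site. With each peak counted only for its nearest start site, 5 of 32 proteasome genes were bound. Heat shock and chaperone genes were bound in 7 of 23 cases, with Hsp27 at 625, Hsp83 at 387, Hsp26 at 315 and Hsc70-4 at 173. Genes of the Notch pathway and E(spl) complex were bound in 7 of 21 cases, among them E(spl)m3-HLH at 437, a peak with no region in replicate 3's relaxed list, E(spl)m7-HLH at 228, mam at 168.5 and neur at 145. Muscle genes were bound in 7 of 26, with Msp300 at 628, mbc at 291, sls at 208 and how at 133.

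Of the genes that mark neural tissue, 2 of 29 were bound for neuronal function, elav at 563 and Nrx-1 at 228, 4 of 23 for neuroblast and proneural genes, numb at 181, brat at 142, pros at 105 and scrt at 103, and 3 of 11 for glia, moody at 467, wrapper at 114 and Gli at 108. Of the phototransduction genes 3 of 23 were bound, rdgC at 458, Fbxl4 at 316 and Galphaq at 168. Of the calmodulin and calcium signalling genes 2 of 24 were bound, Camta at 265 and Calx at 107.6. Segmentation genes were bound in 2 of 27 cases, bcd at 215 and ptc at 109, and homeotic genes in 0 of 8. Trachea and epithelium genes were bound in 4 of 17, dlg1 at 202, crb at 137, sdt at 135 and shg at 117, and genes of gut, fat body and blood in 4 of 19, fkh at 347, Hnf4 at 148, tin at 127 and ush at 95.9.

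**Figure D5:**
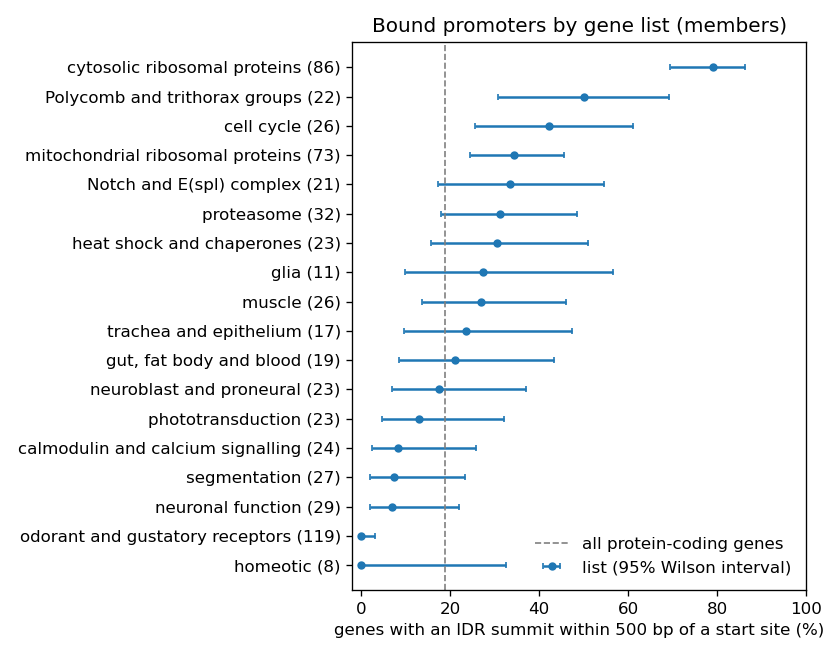
Share of the genes in each fixed list (y axis, members in brackets) with an IDR summit within 500 bp of a start site (x axis, percent); points are shares, bars 95% Wilson intervals and the dashed line the 18.8% of all protein-coding genes. Cytosolic ribosomal proteins stand at 79.1% and odorant and gustatory receptors at 0.

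The X chromosome carried as many peaks per length as the autosomes. IDR peaks lay at 30.7 per Mb on X (722 peaks) and 30.3 per Mb on arms 2L, 2R, 3L and 3R together (3299 peaks), a ratio of 1.01 (95% exact interval 0.934 to 1.1, exact test of 2 rates, two-sided, p = 0.741). Taken per relaxed region, X held 1.09 times as many (Fisher's exact test, p = 0.0293).

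The authors processed the data on 2 genome builds. The IDR list held 4033 peaks on dm6 and 3846 on dm3, and the pooled relaxed list 30000 and 28536 regions. Replicate 3's relaxed list held 29279 regions on dm6 and 24071 on dm3, and replicate 2's 30000 on both. The share of IDR peaks on each arm moved by at most 0.22 percentage points, on X, from 17.9% on dm6 to 18.1% on dm3. Among the strongest 2016 peaks on dm6 and 1923 on dm3, the largest move was -0.251 points, on 3R, from 22.8% to 22.5%. No test was made.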

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

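In this part, the tests of the CGCG box as what holds most peaks and of housekeeping promoters in general were chosen only after the result was seen, and the backgrounds matched on GC content and on start sites were added after the data were examined.

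Regions were listed in a part of the genome that the comparisons above do not use. On dm3, the pooled relaxed list, which includes background candidates, held 43 regions on heterochromatic and unplaced scaffolds, with a signal value of at most 83.5. Of these, 1 had a q value of 0.01 or less, against 19.2% of that whole list, and the IDR list, whose lowest peak had 97.6, held 0 there.

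The CGCG box, which CAMTA proteins bind in vitro, was rarer at summits than in flanks. A reading in which most peaks are held through this box within 50 bp of the summit is excluded by its share of 6.2% (upper Wilson bound 6.99%), far below the 50% that it needs. Base composition stays open: the share was 0.735 times that in dinucleotide-shuffled copies (95% interval 0.651 to 0.828), on both sides of the bound of 0.8 set in advance, and against GC-matched regions the fold was 1.19, with a larger odds ratio for the GCGC control (1.59) than for the CGCG box (1.24). The odds ratio of 0.653 between the strongest and weakest of 4 groups is what signal from a source other than the tagged protein may give. It did not pass among the strongest 2016 peaks (0.754) or among peaks away from promoters (0.907). The groups were not matched on GC content, so the odds ratio cannot tell such signal from base composition. Precipitation from untagged embryos, which would separate such signal from that of the tagged protein, was not analysed here. No other biological explanation was tested.

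Ribosomal protein promoters were bound far more often than other promoters. The mitochondrial ribosomal protein and proteasome genes, taken as other housekeeping lists, did not reach this share. The larger of their shares was 34.2%, and the highest upper bound of both, 48.6%, lay below the lower bound of 69.3% for cytosolic ribosomal proteins. Other housekeeping genes were not examined, so housekeeping promoters in general are not excluded. The number of start sites and close neighbours does not account for the share of the cytosolic list, since 10000 random lists matched on both had a mean share of 24.4% and a maximum of 40.7%. No biological explanation was tested. High transcription of these genes, which can draw unspecific signal, was not tested and stays open.

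Coding exons were nearly absent among the IDR peaks, although they held 19.9% of the other relaxed regions. The AT-rich base composition of the summits does not account for all of it. Within strata of equal GC content and away from promoters, the odds ratio was 0.068 (95% interval 0.0323 to 0.143), below the bound of 0.5 set in advance, against 0.0129 without matching. How the authors' peak caller and control treat coding sequence stays open, and no biological explanation was tested.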

How the results depend on the processing

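The backgrounds matched on GC content and on start sites were chosen only after the data were seen, and the other alternatives before the data were examined. Replicate overlap (70 to 76.9%), replicate correlation (0.688 to 0.773) and the promoter odds ratio (1.51 to 7.36) kept their direction and their side of the threshold under all alternatives run for them. The CGCG fold had the same direction and passed its test at 0.438 to 0.764 in the alternatives tested against flanks or unmatched relaxed regions, except with ACGCGT (0.747, exact McNemar p = 0.235) and AACGCG (0.748, p = 0.0605), and it reversed to 1.19 against GC-matched relaxed regions. In the motif panel the CGCG box missed the required fold with flanks 1000 bp away (0.696) and within 100 bp of the summit (0.708). Without 1 replicate its fold was 0.5 to 0.764 and that of the TATA box 1.39 to 1.75. Motif 1 lost its call among the strongest 2016 peaks (2.67). Against GC-matched relaxed regions the TATA box reversed (0.897), the CCGG control lost its call (0.946) and the CTCF and ETS cores gained one. Other motifs gained a call under some alternatives: GAGA (lower) among the strongest 2016 peaks and without replicate 2, the ETS core (higher) among the strongest 2016 peaks, the heat shock element (higher) without replicate 2, the CTCF core (higher) without replicate 3, the DRE core (higher) with flanks 1000 bp away and the E-box CACGTG (lower) against relaxed regions. The direction of GAGA also depended on the background. GAGA did not differ detectably from GC-matched relaxed regions (10.1% against 9.84%, odds ratio 1.05, 0.932 to 1.17). In dinucleotide-shuffled copies GAGA was less frequent, the summit share being 1.35 times theirs. The CGCG odds ratio between the strongest and weakest of 4 groups no longer passed among the strongest 2016 peaks (0.754) and in peaks away from promoters (0.907). The promoter difference in log10 signal passed among the strongest 2016 peaks (0.0337) and with a 1000 bp window (0.0203), and without 1 replicate it was 0.000526 to 0.0297. The X ratio passed per relaxed region (1.09).

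The number of gene lists called fell from 5 to 2 among the strongest 2016 peaks, where the odds ratios of the lists that lost their call were 1.93 for mitochondrial ribosomal proteins, 1.62 for cell cycle and 2.62 for Polycomb and trithorax groups. With a 1000 bp window it was 3 (mitochondrial ribosomal proteins 1.9, cell cycle 2.67). Among genes with a relaxed region at the promoter it was 1 (mitochondrial ribosomal proteins 1.24, cell cycle 1.55, Polycomb and trithorax groups 2.24, receptors 0). Against random lists matched on start sites it was 2 (1.47, 2.59 and 2.8 in the same order without the receptors). With the nearest start site only, the mitochondrial list lost its call (1.1). Without 1 replicate the cell cycle odds ratio was 2.85 to 4.32. The cause of these changes was not tested. Of the 75 distinct named peaks, 70 were among the 4033 strongest regions without replicate 2, and as many without replicate 3. The X ratio on dm3 was not run, since arm lengths of that build were not used here. No paired analysis was possible because there is 1 group. Read depth is unknown, so the limit it sets on weak peaks is not known either.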

Other observations

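The chromosome 4, 6-mer and gene class comparisons in this part were chosen only after the results were seen, and the test of the head-to-head hypothesis was fixed before its result.

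Chromosome 4 held fewer IDR peaks per length than the major autosomal arms. Its 12 peaks came to 8.9 per Mb, 0.294 times the density of those arms (95% exact interval 0.152 to 0.514, exact test, p = 3.03e-07), while relaxed regions lay at 202.5 per Mb there against 227 on the others. Among non-coding genes, 9 of 32 snRNA genes (28.1%, 95% Wilson interval 15.6 to 45.4) had an IDR summit within 500 bp of a start site. The share was 11 of 290 for tRNA genes (3.79%), 15 of 269 for snoRNA genes (5.58%) and 173 of 3261 for ncRNA genes (5.31%). Of the rRNA genes 0 of 99 were bound (upper Wilson bound 3.74%, which takes the genes as independent). How reads that match several copies of a gene were placed is not known. The 0 therefore cannot be read as absence of binding, and counts of other classes with repeated copies may miss peaks. The snRNA interval holds the 18.8% of protein-coding genes, and the classes were not tested against each other.

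Of the 2080 6-mers, 97 lay in at least 100 summit windows, at least 1.5 times as often as in flanks, and differed from shuffled copies at an adjusted p under 0.05. Among these 97, the highest ratios to shuffled copies were those of ATCGAT and CGATAG, at 6.4% and 6.32% of summits against 2.91% and 2.05% of flanks, both overlapping the DRE sequence. Another word, ACACTG, stood at 9% against 3.69%, 2.36 times its share in shuffled copies.

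Genes with a head-to-head neighbour were bound more often, in 36.4% of 3382 genes against 13.1% of the 10563 others. A candidate explanation is that a window with a pair of promoters is counted for both genes. Counted once per pair in windows of equal width, 35.1% of 1691 pairs were bound against 11% of single promoters, an odds ratio of 4.39 (95% interval 3.9 to 4.93), so double counting does not account for the difference. A pair window still holds the promoters of both genes and is compared with windows of single promoters. Part of the odds ratio can come from more promoters per window, which was not separated. Whether divergent promoters differ in expression or in accessible chromatin was not tested.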
